A study of Mus musculus with 31 samples.

How the data were processed

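Liver RNA of 31 mouse pups (C57Bl/6J, postnatal day 14) was analysed from 1 deposited table. Per the labels' protocols, pups were injected every other day from postnatal day 2 with vehicle, T4, T3 or both. RNA was extracted with TRIzol, and 1 ug of RNA with an integrity number of 7.5 or higher entered a stranded mRNA library kit. The deposited table holds whole-number counts per gene for 43629 genes, which the authors did not normalize as far as the values show. The lowest value in every column is 1, no value is 0 and 50.1% of values are 1, so 1 was added to each count at a step that is not stated. Counts level off near 2 per annotated exonic base, and 108 genes averaged more than 1 count per base. Removal of duplicate reads is not stated. The 37 genes of the mitochondrial chromosome are at 1 in every library. Per the submitters' processing notes, the tools were bcl2fastq, Trimmomatic, BWA 0.7.10 and DESeq, with no role given for each, and the build was GRCh38, a human build, while the column names state mm10. Neither the counting tool, its use of strand nor the annotation version is stated. Of the gene IDs, 42462 (97.3%) are in the GENCODE M21 mouse annotation of mm10, which supplied positions and exonic lengths, while symbols came from the deposited table.

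Groups followed the labels: Dio1KO/Dio2KO pups with a heterozygous Pax8 deletion and vehicle (control, n = 5), and Pax8-null pups of the same background with vehicle (n = 5), T4 (n = 8), T3 (n = 6) or T3+T4 (n = 7). No library was left out of the tests. The design, gene lists, alternatives and rule for naming genes were fixed before the data were examined, apart from the settings named below as added later. Counts as deposited were scaled by the trimmed mean of M-values (TMM), filtered by filterByExpr to 17057 genes and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with 1 mean per group over all 31 libraries and Benjamini-Hochberg adjustment at 0.05. There were 11 comparisons. The 5 main ones were vehicle against control, each of the 3 treatments against vehicle, and T4 against T3. The others were T3+T4 against T4 and against T3, each treatment against control, and the interaction of T3 and T4. Log2 fold changes are given with their SE, group levels as mean ± SD in CPM after TMM scaling. Counts of Pax8, Dio1 and Dio2 are given as deposited. Folds against a vehicle group with 0 to 3 reads after subtraction of the added 1 were taken from pooled reads and library totals. For them, 0 reads were set to a floor of 3 over the group and 1 to 3 reads were given an exact 95% interval, and these intervals and floors cover counting error only.

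Named genes were Pax8, Dio1 and Dio2 in every group. In each main comparison they were also (a) the 5 largest rises and 5 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM over both groups and no overlap between the groups' libraries, and (b) up to 4 members with the smallest adjusted p from each gene list. In each other comparison 3 rises and 3 falls were named by part (a). Features without a symbol, Gm-numbered and Rik clone genes and pseudogene symbols were left out of part (a). The 27 gene lists, written from textbook knowledge, covered thyroid hormone induced genes, hormone transport and deiodinases, lipogenesis, fatty acid oxidation, cholesterol, bile acids, gluconeogenesis and glycogen, the growth hormone and IGF axis, and fetal genes. They also covered drug metabolism, the urea cycle, mitochondrial respiration, the cell cycle, the clock, the acute phase, stress responses, immediate early genes and sex-linked genes, and markers of erythroid, granulocyte, Kupffer, lymphocyte, endothelial, stellate, cholangiocyte, acinar and muscle cells. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 27 lists of a comparison. Slco1c1, Igf2bp1, Lin28b, Cftr, Pnlip, Try4 and Myh4 did not pass the filter and Ahsp was not in the table.

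The alternatives were median-of-ratios factors, scaling by library total alone, no filter on low counts, a mean of at least 5 CPM, fits of the compared groups only, DESeq2 1.42.0, a covariate for sex from Xist and 4 Y-linked genes, animals numbered 54 to 85 only, and leaving out each library in turn. Added after seeing the data were subtraction of the added 1, a correction for the ceiling of 2 counts per exonic base, log2 library total as a covariate, leaving out the 4 animals whose labelled sex differed from their sex genes, acinar and muscle levels as covariates, and leaving out libraries with an acinar or muscle mean of at least 5 CPM. Overlaps between comparisons that share libraries were set beside 20 simulated sets of unchanged groups, the overlap of independent lists, and all 10 ways to split the 5 shared libraries into 2 and 3. For each comparison the group labels were regrouped to give 60 splits of the libraries, the real one included. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

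Library totals ran from 4383769 to 7158919 counts, and the 10 genes with the most counts held 0.97 to 1.3% of a library. Within groups, 84 pairs of replicates had a chi-square per degree of freedom of 2.84 to 25.08, above the 1 that counting error alone gives. The 5 pairs with T3 animal 61 had 15.58 to 25.08, the other pairs of T3 livers 5.81 to 11.25, and the highest pair without that animal 15.98. The tests were run on simulated data for 17057 genes with 200 of them changed. At 1.5-fold, 2-fold and 4-fold the recovered percentages were 58.2, 70.1 and 93.9 for vehicle against control, and 62.7, 82.1 and 98.5 for T4, 49.3, 86.6 and 97 for T3 and 62.7, 77.6 and 97 for T3+T4 against vehicle. They were 56.7, 85.1 and 95.5 for T4 against T3, 68.7, 85.1 and 93.9 for T3+T4 against T4, and 59.7, 79.1 and 97 for T3+T4 against T3. Against control they were 68.7, 82.1 and 100 for T4, 53.7, 74.6 and 95.5 for T3 and 55.2, 85.1 and 97 for T3+T4, and for the interaction 29.9, 65.7 and 87.9. Each comparison made 3 to 12 false calls. Of the 11 simulated lists of 20 members changed 1.25-fold, 11 were called, with 0 calls of unchanged lists at an unadjusted p under 0.05. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes.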

Results

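Gene expression was measured by RNA sequencing in the livers of 31 mouse pups at postnatal day 14. All pups lacked type 1 and type 2 deiodinase, the enzymes that convert thyroxine (T4) into the receptor ligand T3 (genotype Dio1KO/Dio2KO). Control pups also carried 1 intact copy of Pax8, a transcription factor needed to form the thyroid, and received vehicle (5 livers, called control). The other pups lacked Pax8 and are called triple mutants. They received vehicle (5 livers, called vehicle), T4 (8 livers), T3 (6 livers) or both hormones (7 livers, called T3+T4), every other day from postnatal day 2. The design asks what T4 does to the neonatal liver when neither of these deiodinases can convert it. Library totals ran from 4383769 to 7158919 counts. They averaged 5413170 ± 395846 in control (SD, n = 5), 5297107 ± 301534 in vehicle (n = 5), 5343109 ± 528829 after T4 (n = 8), 6070280 ± 481634 after T3 (n = 6) and 6353684 ± 534439 after T3+T4 (n = 7). The T3 and T3+T4 libraries were thus the larger ones. Per library, 20954 to 22975 genes had a count above 1, the lowest value in the table. Of the animals numbered 54 to 85, 6 of the 6 T3 and 7 of the 7 T3+T4 animals belong to this later range, against 5 of 8 T4, 2 of 5 vehicle and 1 of 5 control animals.

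The genes removed by design showed the following counts. Dio1 (ENSMUSG00000034785, chromosome 4, 107291465 to 107307169 in mm10) is itself a thyroid hormone target in liver. Reads were still assigned to it in every library, with a mean deposited count of 891.6 ± 118.6 in control (SD, n = 5) and 65 ± 19.7 in vehicle (n = 5). After hormone the mean count of Dio1 was 184.9 ± 96 with T4 (n = 8), 834.3 ± 353.4 with T3 (n = 6) and 1187.9 ± 286.3 with T3+T4 (n = 7). The labels do not say which part of the gene is deleted. Pax8 (ENSMUSG00000026976, chromosome 2, 24420560 to 24475599) had mean counts of 5.8 in control and 8.8, 15, 11.3 and 11.1 in vehicle, T4, T3 and T3+T4 livers. Dio2 (ENSMUSG00000007682, chromosome 12, 90724552 to 90738438) had mean counts of 17, 15.4, 16.9, 17.7 and 18 in the same order. Neither Pax8 nor Dio2 passed the test in any comparison, and whether depth limits this was not tested. The log2 fold change of Pax8 between T4 and control livers was 1.32 (95% interval 0.45 to 2.2, adjusted p = 0.08 with edgeR).

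Without a thyroid, 7 of 17 thyroid hormone induced, 10 of 20 lipogenesis and 11 of 24 cholesterol genes were lower in triple mutant livers and 5 of 11 fetal liver genes were higher. The calls of the cholesterol and fetal lists were lost with an estimated correlation (adjusted p = 0.262 and adjusted p = 0.181). Dlk1 (ENSMUSG00000040856), an imprinted gene of the fetal liver, rose from 5.58 ± 3.17 CPM (counts scaled to a common library total) in control to 58.1 ± 15.7 in vehicle livers (SD, n = 5 each), a log2 fold change of 3.36 ± 0.44 (SE, adjusted p = 1.06e-05). Ntrk2 (ENSMUSG00000055254), the receptor for brain-derived neurotrophic factor, fell from 129 ± 74.9 to 5.54 ± 3.5 CPM, a log2 fold change of -4.54 ± 0.75 (adjusted p = 0.000272). The pseudogene 9030619P08Rik, chosen after its values were seen, fell from 93.7 ± 13 to 3.59 ± 2.28 CPM (log2 fold change -4.71 ± 0.29, adjusted p = 8.7e-12). Of 17057 genes tested, 839 were higher and 803 lower in vehicle than in control livers. Genes that rose under the fixed rule for naming genes included Slc4a9, a bicarbonate transporter (4.02 ± 1.03), Tuba8, a tubulin (2.71 ± 0.44), Cxcr2, a chemokine receptor of neutrophils (2.67 ± 0.49), and Gprc5b, an orphan receptor (2.53 ± 0.34). Those that fell included the amylase gene Amy2a1 (-3.74 ± 0.55), Dio1 (-3.74 ± 0.34), Csrp3, a muscle LIM protein (-3.45 ± 0.48), and Col4a3, a basement membrane collagen (-3.41 ± 0.68). Leaving out control animal 49, control animal 50 or vehicle animal 38 left 966, 935 or 1011 genes called, and leaving out every library with a raised pancreatic acinar or muscle mean left 689.

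Of 17 thyroid hormone induced genes, 0 rose, 7 fell and 10 did neither in vehicle livers, and adjusted over the list alone 2 rose and 9 fell (median log2 fold change -0.43, camera adjusted p = 1.55e-06, and 0.00937 with an estimated correlation). Me1, a malic enzyme that supplies NADPH, fell by 1.39 ± 0.39, Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase, by 1.43 ± 0.32, and Bcl3 by 1.15 ± 0.22 on the log2 scale. Of 20 de novo lipogenesis genes, 10 fell and 0 rose, the same 10 and 0 in number when adjusted over the list alone (median -0.34, camera adjusted p = 4.95e-07, and 0.0177 with an estimated correlation). Fasn, the fatty acid synthase, fell by 1.24 ± 0.20 and Acaca, an acetyl-CoA carboxylase, by 0.31 ± 0.08. Thrsp, a regulator of fatty acid synthesis chosen after its values were seen, fell from 34.3 ± 26.5 to 2.88 ± 1.11 CPM (SD, n = 5 each, adjusted p = 0.00848). Of 24 cholesterol synthesis and uptake genes, 11 fell and 0 rose, and 17 fell adjusted over the list alone (median -0.78, camera adjusted p = 9.28e-11). That list had an adjusted p = 0.262 with an estimated correlation. Msmo1, a sterol methyl oxidase, fell by 1.88 ± 0.38, Hmgcs1, an enzyme of the early mevalonate pathway, by 1.12 ± 0.19, and Srebf2, the transcription factor of cholesterol synthesis genes, by 0.79 ± 0.16. The call of Me1 was lost without control animal 47, 49 or 50 or vehicle animal 55, and that of Acaca without control animal 49 or vehicle animal 37 or 38 (adjusted p up to 0.227 and 0.0724 over all settings).

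In the same comparison 5 of 11 fetal and neonatal liver genes rose, 0 fell and 6 rose adjusted over the list alone (median 0.53, camera adjusted p = 9.97e-05, but adjusted p = 0.181 with an estimated correlation). They included the imprinted genes Peg3 (0.91 ± 0.29) and Plagl1 (0.90 ± 0.22) and the proteoglycan gene Gpc3 (0.53 ± 0.17). Of 25 fatty acid oxidation and ketogenesis genes, 4 rose, 0 fell and 5 rose adjusted over the list alone (median 0.11, camera adjusted p = 0.013, adjusted p = 0.778 with an estimated correlation). The omega-hydroxylase genes Cyp4a10 (1.15 ± 0.29) and Cyp4a14 (0.60 ± 0.15) were among them. Of 13 growth hormone and IGF axis genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.00183, adjusted p = 0.102 with an estimated correlation). Stat5a, which carries the growth hormone signal, fell from 84.2 ± 11.4 to 35.4 ± 4.11 CPM (SD, n = 5 each) and the prolactin receptor gene Prlr fell by 1.05 ± 0.23. Of 19 cell cycle genes, 4 fell and 0 rose, with 17 lower adjusted over the list alone (median -1.04, camera adjusted p = 2.04e-09, adjusted p = 0.413 with an estimated correlation). Cenpa, a centromeric histone, fell by 0.89 ± 0.24. Of 23 genes of thyroid hormone transport, binding, receptors and deiodinases, 4 rose and 2 fell, both in all and adjusted over the list alone (camera adjusted p = 0.805). The carrier gene Slco1a1 (1.99 ± 0.38), the T4-binding globulin gene Serpina7 (1.29 ± 0.26), the receptor gene Thra (0.37 ± 0.07) and Dio3, the deiodinase that inactivates both hormones (1.36 ± 0.40), rose. Dio3os, a transcript antisense to Dio3, rose 2.83-fold, from 19.2 ± 8.98 to 54.7 ± 9.94 CPM (SD, n = 5 each), and whether reads were assigned by strand is not stated. Of 13 immediate early and heat shock genes, which respond to handling, 3 rose and 0 fell, with 4 higher adjusted over the list alone (camera adjusted p = 0.0455, adjusted p = 0.717 with an estimated correlation). Nr4a1 (2.29 ± 0.66) and Ier3 (0.92 ± 0.23) were among the 3. Leaving out 1 library ended the calls of Cenpa (vehicle animal 38), of Nr4a1 (control animals 42, 47, 49 or 50, vehicle animals 37 or 55), and of Dio3, Dio3os, Gpc3 and Peg3 (each with control animal 49 or 50 or vehicle animal 38 or 2019, among others), with adjusted p up to 0.186 over all settings.

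Other lists held few calls between vehicle and control livers. Of 18 bile acid genes 3 rose and 2 fell (camera adjusted p = 0.522), among them Abcg8, a sterol exporter (0.47 ± 0.12), and Cyp8b1, a bile acid hydroxylase (-0.56 ± 0.12). Of 16 gluconeogenesis and glycogen genes 2 rose and 1 fell (camera adjusted p = 0.438), with the glycogen synthase gene Gys2 at 0.64 ± 0.16 and Ugp2 at 0.28 ± 0.08 (lost without control animal 47, 49 or 50 or vehicle animal 37, 38 or 55). Of 20 drug metabolism genes 1 rose (camera adjusted p = 0.194), of 15 urea cycle and amino acid genes 1 rose and 1 fell (0.0612), of 24 mitochondrial respiration genes 1 fell (0.488), and of 12 stress response genes 1 rose and 1 fell (0.44). The urea cycle carrier gene Slc25a13 rose by 0.27 ± 0.06. Of 16 circadian clock genes 2 rose, Tef (0.47 ± 0.11) and Cry2 (0.33 ± 0.08), with a camera adjusted p of 0.233. Of 10 endothelial genes 2 rose and 1 fell (0.44), and Kdr, a VEGF receptor, rose by 0.36 ± 0.09. Of 12 stellate cell genes 2 fell (0.182) and of 11 Kupffer cell genes 1 fell (0.0529). With edgeR, 0 genes passed among 15 acute phase (camera adjusted p = 0.245), 11 erythroid (0.182), 10 granulocyte (0.0455, adjusted p = 0.778 with an estimated correlation), 11 lymphocyte (0.975), 7 cholangiocyte (0.463), 7 skeletal muscle (0.465) and 5 sex-linked genes (0.425). Of 8 pancreatic acinar genes, 2 fell, the elastase gene Cela1 (-0.80 ± 0.17) and Amy2a5 (-2.70 ± 0.59), although the median of the list was 1.35, its mean 0.73 and the direction of camera downward (adjusted p = 0.615). The mean of the other acinar genes was at least 5 CPM in 1 of 5 control and 2 of 5 vehicle libraries. Amy2a1, Amy2a2, Amy2a4 and Amy2a5 are close paralogs, so the assignment of reads among them is uncertain.

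**Figure D1:**
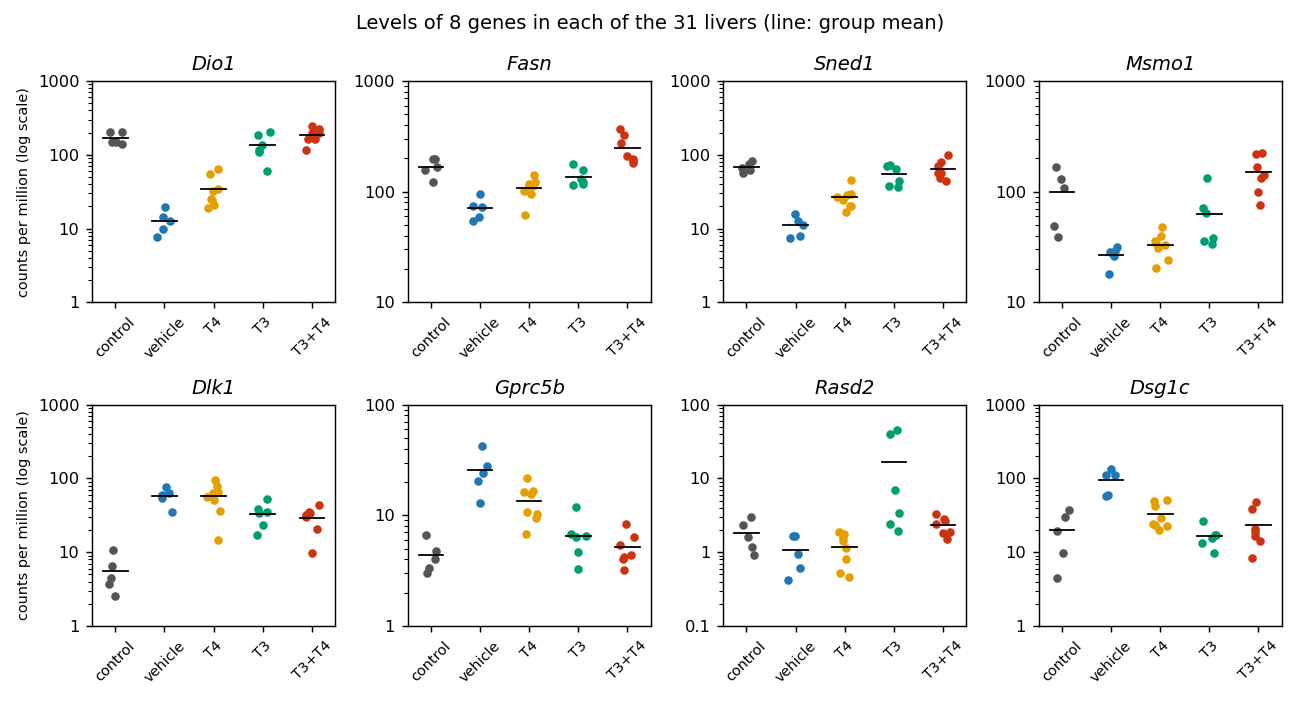
CPM (log scale) of 8 genes in each of the 31 livers, with a line at each group mean. Dio1 averaged 169 in control, 12.7 in vehicle, 34.3 after T4, 135 after T3 and 187 after T3+T4, while Rasd2 averaged 16.6 after T3 and 2.35 after T3+T4.

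**Figure D2:**
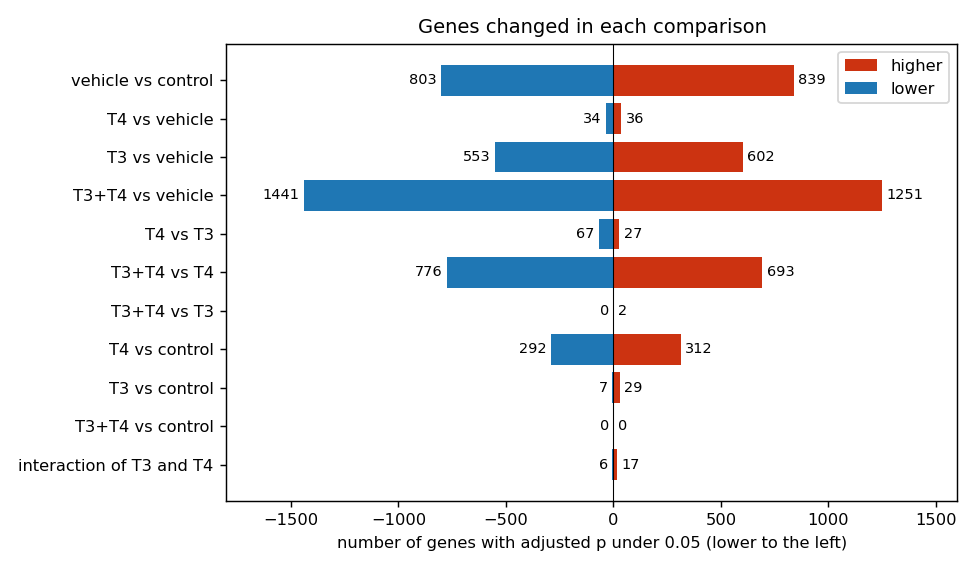
Number of genes higher (right) and lower (left) at an adjusted p under 0.05 in each comparison. T3+T4 against vehicle had 1251 higher and 1441 lower genes, and T4 against vehicle had 36 and 34.

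T4 alone changed 70 genes in triple mutant livers, and 63 of them were also called after T3 in the same direction. The pseudogene 9030619P08Rik (ENSMUSG00000053168), chosen after its values were seen, rose from 3.59 ± 2.28 CPM in vehicle (SD, n = 5) to 42.6 ± 13.5 after T4 (n = 8), an 11.9-fold rise (log2 fold change 3.57 ± 0.28, adjusted p = 4.14e-09). Akr1c18, a steroid dehydrogenase, rose 5.91-fold from 3.56 ± 1.24 to 21.2 ± 7.57 CPM (2.56 ± 0.49, adjusted p = 0.0135). Trim7, a ubiquitin ligase, rose 2.66-fold (1.41 ± 0.24, adjusted p = 0.00396), Tlcd2 2.42-fold (1.27 ± 0.18, adjusted p = 0.000219), Sned1 2.40-fold (1.26 ± 0.26, adjusted p = 0.0261) and Sbk1, a kinase, 1.87-fold (0.90 ± 0.11, adjusted p = 7.89e-05). Nt5e, which makes adenosine, Abhd6, a lipid hydrolase, and Cyp3a44, a cytochrome P450 with close paralogs, rose by 0.82 ± 0.11, 0.64 ± 0.12 and 1.93 ± 0.28, and were chosen after their values were seen. Genes that fell included Dsg1c, a desmoglein (-1.54 ± 0.36, adjusted p = 0.0474), Ank3, an ankyrin (-0.73 ± 0.13), Nr5a2, a nuclear receptor of bile acid synthesis (-0.56 ± 0.09), Slc22a15 (-0.53 ± 0.12) and Tfdp2, a partner of E2F factors (-0.52 ± 0.11). Csrp3 (2.41 ± 0.47) and Dio1 (1.44 ± 0.32, adjusted p = 0.041) also rose, and the antisense transcript 1810064F22Rik, chosen after its values were seen, fell by 1.16 ± 0.24. In all, 36 genes rose and 34 fell with edgeR (58 and 26 when scaled by the library total alone). Leaving out vehicle animals 37, 38 or 55 left 16, 18 or 14 genes, and leaving out T4 animals 43, 58, 69, 70 or 71 left 36, 33, 37, 38 or 31. Only animals 54 to 85 gave 8 genes, no filter 34, acinar and muscle covariates 22, leaving out libraries with raised acinar or muscle genes 1 (9030619P08Rik), and DESeq2 235. T4 animals 40, 43 and 46 lay nearest to the mean of control, T3 and vehicle livers, and T4 animals 54, 58, 69, 70 and 71 nearest to that of T4 livers.

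Among the 21 named genes called after T4, 8 stayed called without any 1 library: 9030619P08Rik, Nt5e, Cyp3a44, Sbk1, Tlcd2, Trim7, Nr5a2 and Ank3. Dio1, Akr1c18, Sned1, Abhd6, Csrp3 and 1810064F22Rik were lost without vehicle animal 37 or 55, and the remaining 7 without at least 1 library. The call of 9030619P08Rik held under all 27 other settings, with adjusted p from 4.41e-41 to 0.00598. Of 20 lipogenesis genes 2 rose, Fads1 (0.41 ± 0.09) and Fads2 (0.34 ± 0.08), which desaturate fatty acids, and 6 rose adjusted over the list alone (median 0.31, camera adjusted p = 1.4e-05, adjusted p = 0.0836 with an estimated correlation). Of 17 thyroid hormone induced genes 1 rose, Dio1, with 5 higher and 2 lower adjusted over the list alone (median 0.22, camera adjusted p = 0.0112, adjusted p = 0.348 with an estimated correlation). Of 24 cholesterol genes 1 rose, the sterol desaturase gene Sc5d (0.50 ± 0.12), with a camera adjusted p of 0.0736. With edgeR, 0 genes passed among 15 urea cycle genes (median -0.22, camera adjusted p = 0.000221, adjusted p = 0.47 with an estimated correlation), 19 cell cycle genes (median 0.52, camera adjusted p = 5.06e-05, adjusted p = 0.488 with an estimated correlation) and 11 Kupffer cell genes (median 0.21, camera adjusted p = 1.4e-05, adjusted p = 0.39 with an estimated correlation). Over all genes in this comparison 2167 had an unadjusted p under 0.05. Of 8 acinar genes 1 fell, the colipase gene Clps (-4.44 ± 1.04, a call lost in 17 of 24 other settings, the added 1 subtracted among them, with adjusted p from 0.00496 to 0.911), and 5 were lower adjusted over the list alone (median -3.68, camera adjusted p = 0.00126, adjusted p = 0.39 with an estimated correlation). With edgeR 0 of 7 skeletal muscle genes passed, while 7 were higher adjusted over the list alone (median 3.68, camera adjusted p = 0.000262, adjusted p = 0.39 with an estimated correlation). The mean of the muscle list was at least 5 CPM in 3 of 8 T4 and 0 of 5 vehicle libraries.

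T3 alone raised 6 of 17 thyroid hormone induced genes and 7 of 20 lipogenesis genes (1 fell) and lowered 5 of 25 fatty acid oxidation genes. The calls of the lipogenesis and oxidation lists were lost with an estimated correlation (adjusted p = 0.122 and adjusted p = 0.521), and 1 oxidation gene was lower with the library total as a covariate. The muscle LIM protein gene Csrp3 rose 12.7-fold, from 0.843 ± 0.422 CPM in vehicle (SD, n = 5) to 11 ± 5.85 after T3 (n = 6, log2 fold change 3.67 ± 0.46, adjusted p = 1.11e-05). Akr1c18 rose 15.1-fold (3.91 ± 0.49, adjusted p = 1.11e-05), Sult5a1, a sulfotransferase, 17.5-fold (4.13 ± 0.67, adjusted p = 0.000441) and Rasd2 (ENSMUSG00000034472), a small GTPase, 15.1-fold (3.92 ± 0.70, adjusted p = 0.00103). Rasd2 was not called after T3+T4 against vehicle (1.12 ± 0.72, adjusted p = 0.312). Ckm, the muscle creatine kinase, rose by 5.30 ± 1.48 (adjusted p = 0.0281). Ckm had 4 reads above the added 1 over the vehicle livers, and its log2 fold change was 6.35 with the 1 subtracted. That call was lost without any 1 of the 5 vehicle animals or T3 animal 60 or 64 (adjusted p up to 0.332). Genes that fell included Dsg1c (-2.53 ± 0.41), Ugt1a9, a glucuronosyltransferase whose exons overlap those of its family (-2.11 ± 0.34), Ces1f, a carboxylesterase (-1.96 ± 0.44), Gprc5b (-1.95 ± 0.30) and Slc2a5, the fructose transporter (-1.91 ± 0.34). Of the 17057 genes, 602 rose and 553 fell (801 and 408 when scaled by the library total alone). Leaving out vehicle animals 37, 38 or 55 left 622, 744 or 677 genes. With the library total as a covariate 524 genes were called, with animals 54 to 85 only 167, with the sex covariate 587, with acinar and muscle covariates 463, and without the libraries with raised acinar or muscle genes 83.

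Of 17 thyroid hormone induced genes, 6 rose, 0 fell and 11 did neither after T3, with 8 higher and 1 lower adjusted over the list alone (median 0.54, camera adjusted p = 5.99e-07, and 0.00421 with an estimated correlation). Dio1 rose 10.7-fold (3.41 ± 0.33), Me1 4.02-fold (2.01 ± 0.38) and Gpd2 2.54-fold (1.35 ± 0.31). Of 20 lipogenesis genes 7 rose and 1 fell, with 10 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 0.000207, adjusted p = 0.122 with an estimated correlation). Fasn rose by 0.94 ± 0.20 and Acaca by 0.35 ± 0.08. Of 24 cholesterol genes 3 rose and 0 fell, with 4 adjusted over the list alone (median 0.33, camera adjusted p = 0.0035, adjusted p = 0.604 with an estimated correlation). Hmgcs1 rose by 0.63 ± 0.18 and Msmo1 by 1.23 ± 0.37. The call of Hmgcs1 was lost without vehicle animal 37, 38 or 67 or T3 animal 60 or 68, and that of Msmo1 without any 1 of the 5 vehicle animals or T3 animal 60, 61 or 68 (adjusted p up to 0.25 and 0.337). Of 25 fatty acid oxidation genes 5 fell, with 8 lower adjusted over the list alone (median -0.18, camera adjusted p = 0.000238, adjusted p = 0.521 with an estimated correlation), and Acadm, a medium-chain acyl-CoA dehydrogenase, fell by 0.36 ± 0.07. Of these 25 genes 1 was lower with the library total as a covariate. Of 20 drug metabolism genes 2 fell and 9 were lower adjusted over the list alone (camera adjusted p = 0.000238, adjusted p = 0.521 with an estimated correlation). Of these 20 genes 0 passed once the library total was a covariate (camera adjusted p = 0.297). Of 15 urea cycle genes 1 fell, Slc25a13 (-0.30 ± 0.06), with a camera adjusted p of 0.00719 (adjusted p = 0.604 with an estimated correlation) that became 0.92 with that covariate.

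After T3, 5 of 23 hormone transport and deiodinase genes fell and 3 rose (3 and 6 adjusted over the list alone, camera adjusted p = 0.223). Dio3 fell by 1.55 ± 0.37 and Serpina7 by 0.89 ± 0.25, while Slc16a10, an amino acid and T3 transporter, rose by 1.38 ± 0.35. Of 11 fetal genes 1 fell, with 2 lower adjusted over the list alone (median -0.35, camera adjusted p = 0.00109, adjusted p = 0.38 with an estimated correlation). Of 11 Kupffer cell genes 1 rose, Timd4 (0.56 ± 0.17), and 8 were higher adjusted over the list alone (camera adjusted p = 7.45e-06, adjusted p = 0.382 with an estimated correlation). Of 16 clock genes 1 fell, Tef (-0.49 ± 0.11), and 3 were lower adjusted over the list alone (camera adjusted p = 0.0453, adjusted p = 0.38 with an estimated correlation). Of 13 growth hormone and IGF genes 2 rose, Stat5a (0.92 ± 0.14) and Prlr (0.79 ± 0.22), with a camera adjusted p of 0.241. Of 7 muscle genes 6 rose and 7 were higher adjusted over the list alone (median 4.44, camera adjusted p = 0.00109, adjusted p = 0.521 with an estimated correlation). Acta1, the skeletal muscle actin, averaged 57.4 ± 79.6 CPM after T3 (SD, n = 6) and 1.52 ± 1.63 in vehicle (n = 5), the muscle mean was at least 5 CPM in 2 of 6 T3 libraries, and 0 muscle genes passed with the library total as a covariate. Of 8 acinar genes 5 fell, also adjusted over the list alone (camera adjusted p = 0.254), among them Ctrb1, a chymotrypsinogen (6 reads after T3 against 522 in vehicle), and Cel, a lipase of pancreatic juice (1 read against 309). Leaving out 1 library ended the calls of Ctrb1 and Cel (vehicle animal 37, and for Cel T3 animal 60 or 64), Slc16a10 (T3 animal 61), Serpina7 (vehicle animal 67, T3 animal 60 or 61), Prlr (vehicle animal 38 or 67, T3 animal 60 or 65) and Timd4 (vehicle animal 37, 38, 55 or 67, T3 animal 61, 62, 65 or 68), with adjusted p up to 0.708. The acinar mean was at least 5 CPM in 0 of 6 T3 and 2 of 5 vehicle libraries.

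Of the 3 treatments, T3+T4 had the most genes called against vehicle. The direct test of T3+T4 against T3 called 2 genes. The median absolute log2 change of the genes called against vehicle was 0.44 after T3+T4 and 0.55 after T3. The lipase gene Lipg rose 30.5-fold, from 0.438 ± 0.382 CPM in vehicle (SD, n = 5) to 13.8 ± 11.4 after T3+T4 (n = 7, log2 fold change 4.93 ± 0.72, adjusted p = 3.46e-05). Serpina9 rose 27.9-fold (4.80 ± 0.70) and Dio1 14.7-fold (3.88 ± 0.33). Lipg had 6 reads and Serpina9 4 above the added 1 over the vehicle livers, and with the 1 subtracted their log2 fold changes were 5.73 and 5.85. A1bg had 0 reads above the added 1 in vehicle livers and was at least 81.5-fold higher (411 reads, against a floor of 3 reads over the group). Ces4a had 370 reads against 2, a 110-fold ratio (95% counting interval 30.2 to 912), and Slc6a11, a GABA transporter gene, 536 against 1, a 319-fold ratio (57 to 12600). Genes that fell included Slc4a9 (-4.63 ± 0.93), Vldlr, a lipoprotein receptor (-3.01 ± 0.37), Gprc5b (-2.30 ± 0.29), Osbpl3, a lipid transfer protein (-2.27 ± 0.40), and Dio3os (-2.24 ± 0.42). Of the 17057 genes, 1251 rose and 1441 fell (1670 and 1105 when scaled by the library total alone). The count was 794 with animals 54 to 85 only and 685 without the libraries with raised acinar or muscle genes, and no single left-out library moved it beyond 1879 to 2831.

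Of 17 thyroid hormone induced genes, 9 rose, 1 fell and 7 did neither after T3+T4, with 9 and 2 adjusted over the list alone (median 0.56, camera adjusted p = 2.05e-08, and 0.00201 with an estimated correlation). Thrsp rose from 2.88 ± 1.11 to 66.2 ± 54.2 CPM (SD, n = 5 and 7, log2 fold change 4.51 ± 0.83) and Me1 rose by 2.03 ± 0.37. Of 20 lipogenesis genes 9 rose and 0 fell, with 13 adjusted over the list alone (median 0.48, camera adjusted p = 7.35e-10, and 0.00295 with an estimated correlation). Fasn rose by 1.81 ± 0.20, Aacs, a cytosolic ketone-activating ligase, by 1.98 ± 0.25 and Acaca by 0.56 ± 0.08. Of 24 cholesterol genes 18 rose and 0 fell, with 20 adjusted over the list alone (median 1.11, camera adjusted p = 6.95e-22, adjusted p = 0.0614 with an estimated correlation). Msmo1 rose by 2.50 ± 0.37, Hmgcs1 by 1.19 ± 0.18, Srebf2 by 1.01 ± 0.15 and Sc5d by 0.87 ± 0.12. Of 11 fetal genes 8 fell and 0 rose, also adjusted over the list alone (median -0.68, camera adjusted p = 9.77e-06, adjusted p = 0.101 with an estimated correlation). Peg3 fell by 1.20 ± 0.26, the alpha-fetoprotein gene Afp by 1.12 ± 0.23, Dlk1 by 0.99 ± 0.34 and Gpc3 by 0.68 ± 0.16. The call of Dlk1 was lost without vehicle animal 2019, 37, 38 or 67 or T3+T4 animal 72, 77, 84 or 85 (adjusted p up to 0.315). Of these 11 genes 5 fell with the library total as a covariate.

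Of 25 fatty acid oxidation genes, 12 fell and 0 rose after T3+T4, with 13 adjusted over the list alone (median -0.26, camera adjusted p = 1.96e-07, adjusted p = 0.391 with an estimated correlation). Cyp4a10 fell by 1.16 ± 0.26, Cyp4a14 by 0.88 ± 0.14 and Acadm by 0.49 ± 0.07, and with the library total as a covariate 6 fell. Of 20 drug metabolism genes 8 fell and 1 rose (1 and 11 adjusted over the list alone, camera adjusted p = 0.0022, adjusted p = 0.63 with an estimated correlation). They included Nr1i3, a xenobiotic receptor (-0.51 ± 0.12), and Gstm1, a glutathione transferase (-0.50 ± 0.12). With that covariate 2 fell and 1 rose (camera adjusted p = 0.965). Of 16 gluconeogenesis and glycogen genes 6 fell and 1 rose (camera adjusted p = 0.0425, adjusted p = 0.63 with an estimated correlation, 0.765 with the covariate). Gys2 fell by 0.63 ± 0.15 and Pcx, the pyruvate carboxylase, by 0.40 ± 0.06. Of 15 acute phase genes 6 fell and 1 rose (camera adjusted p = 0.0346, adjusted p = 0.68 with an estimated correlation), with the fibrinogen gene Fgb at -0.30 ± 0.07, and with the covariate 0 fell and 2 rose. Of 15 urea cycle genes 2 fell and 1 rose (camera adjusted p = 0.00662, adjusted p = 0.68 with an estimated correlation, 0.765 with the covariate). Alb, the albumin gene, chosen after its values were seen, fell by 0.24 ± 0.08 and was at 0.01 with the covariate (adjusted p = 0.902). Its call was also lost without vehicle animal 38 or 55 or T3+T4 animal 77, 78 or 84.

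**Figure D3:**
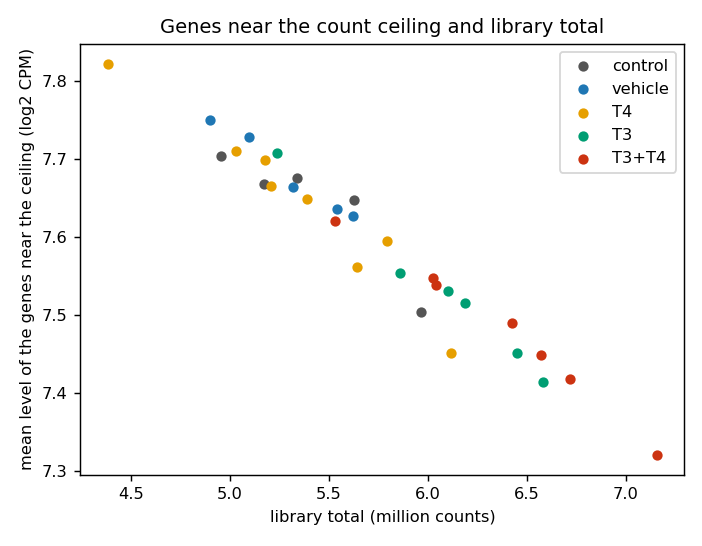
Mean level of the 106 genes above 50% of the count ceiling against the library total in each of the 31 livers. The slope within groups was -0.76 (95% interval -0.84 to -0.67) in log2 CPM per doubling of the library total.

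In the comparison of T3+T4 with vehicle livers 6 of 23 hormone transport and deiodinase genes fell and 2 rose, with 4 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.211). Dio3 fell by 2.21 ± 0.37, Slco1a1 by 2.04 ± 0.34 and Serpina7 by 1.45 ± 0.24. Abcc3, a conjugate exporter, fell by 2.14 ± 0.24. Of 13 growth hormone and IGF genes 4 rose and 3 fell (camera adjusted p = 0.294), with Stat5a at 1.19 ± 0.14. Of 18 bile acid genes 4 rose and 4 fell (camera adjusted p = 0.831), with Cyp8b1 at 0.42 ± 0.11 and Abcg8 at -0.56 ± 0.11. Of 19 cell cycle genes 3 rose (median 0.73, camera adjusted p = 2.1e-05, adjusted p = 0.63 with an estimated correlation), with Cenpa at 0.69 ± 0.23, and with the covariate 0 passed. Of 10 endothelial genes 2 fell (camera adjusted p = 0.0332, adjusted p = 0.63 with an estimated correlation), Kdr among them (-0.27 ± 0.08). The call of Cenpa was lost without vehicle animal 38, 55 or 67 or T3+T4 animal 77 or 80, and that of Kdr without vehicle animal 2019 or 67 or T3+T4 animal 72 or 85 (adjusted p up to 0.277 and 0.173). Of 8 acinar genes 2 rose, Cela1 (0.97 ± 0.15) and Amy2a5 (2.88 ± 0.57), with a camera adjusted p of 0.139. The mean of the other acinar genes was at least 5 CPM in 3 of 7 T3+T4 and 2 of 5 vehicle libraries, and that of muscle genes in 2 of 7 and 0 of 5.

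**Figure D4:**
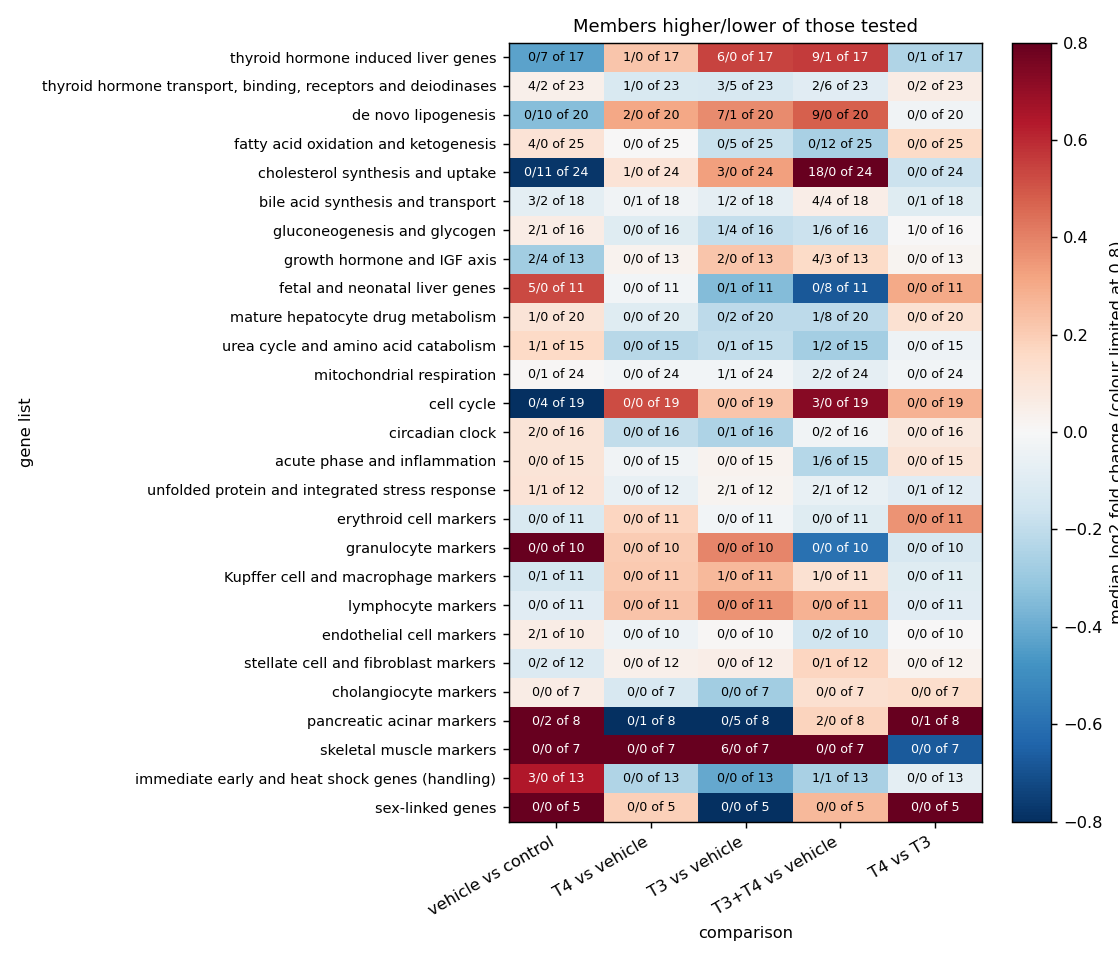
Median log2 fold change (colour, limited at 0.8) of each of the 27 gene lists in 5 comparisons, with the number of members higher/lower of those tested. Of the 24 cholesterol genes, 11 were lower in vehicle than in control livers and 18 were higher after T3+T4 than after vehicle.

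T4 and T3 differ by 1 iodine, and 94 genes differed between T3 and T4 livers. Among them were Dio1, amylase genes and the transporter gene Slc16a10, whose call was lost without T3 animal 61. The labels do not give the doses, so it is unknown whether they matched. Xist was expressed in 2 of 8 T4 and 5 of 6 T3 libraries, so these groups also differed in sex. Dio1 averaged 34.3 ± 16.7 CPM after T4 (SD, n = 8) and 135 ± 53.2 after T3 (n = 6), a log2 difference (T4 minus T3) of -1.97 ± 0.25 (adjusted p = 0.000241). Rasd2 averaged 1.19 ± 0.547 and 16.6 ± 20.1 CPM (-3.77 ± 0.57, adjusted p = 0.00241), Sult5a1 1.59 ± 0.894 and 12.5 ± 7.78 CPM (-2.94 ± 0.50, adjusted p = 0.00303) and Amy2a1 2.17 ± 1.26 and 15.1 ± 12.5 CPM (-2.83 ± 0.46, adjusted p = 0.00263). Other genes lower after T4 were Rap1gap2, a GTPase activator (-1.22 ± 0.20), Pdp2, a pyruvate dehydrogenase phosphatase (-0.80 ± 0.16), and Frmd8 (-0.60 ± 0.12). Those higher after T4 than after T3 included Fam83a (1.84 ± 0.34), Cyp2c67, a cytochrome P450 with close paralogs (0.97 ± 0.16), Marveld1 (0.43 ± 0.10), Kank2 (0.42 ± 0.10) and Pcx (0.30 ± 0.06). The call of Frmd8 was lost without T3 animal 68, that of Pdp2 without T3 animal 61 or 68, and those of Marveld1 and Kank2 without T4 animal 69, 70 or 71 or T3 animal 60, 61 or 64, among others (adjusted p up to 0.509). In all 27 genes were higher and 67 lower after T4 than after T3. T3 animal 61 stood apart from the other T3 livers, with a chi-square per degree of freedom of 15.58 to 25.08 in its pairs against 5.81 to 11.25 in the other pairs. Leaving out T4 animals 69 or 70 or T3 animals 61, 62 or 68 gave 42, 41, 41, 342 or 27 genes. The count was 43 with animals 54 to 85 only, 21 with the library total as a covariate, 8 with the sex covariate, 234 with DESeq2, and 0 without the libraries with raised acinar or muscle genes.

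Of 17 thyroid hormone induced genes, 1 was lower after T4 than after T3 (Dio1) and 0 higher, with 6 lower adjusted over the list alone (median -0.24, camera adjusted p = 4.4e-06, and 0.0103 with an estimated correlation). Of 23 transport and deiodinase genes 2 were lower, Dio1 and Slc16a10 (-1.49 ± 0.30), a call lost without T3 animal 61 (adjusted p from 0.000963 to 0.327 over its 28 other settings). With edgeR 0 of 25 fatty acid oxidation genes passed, with 5 higher adjusted over the list alone (median 0.15, camera adjusted p = 3.26e-06, adjusted p = 0.466 with an estimated correlation). With edgeR 0 of 11 fetal genes (camera adjusted p = 0.00175, adjusted p = 0.435 with an estimated correlation), 11 erythroid genes (0.00456, adjusted p = 0.711) and 19 cell cycle genes (0.00252, adjusted p = 0.905) passed. Several genes called after T4 were not called between the hormones. The T4 minus T3 difference of Sbk1 was -0.17 (95% interval -0.38 to 0.04), that of Nr5a2 -0.11 (-0.29 to 0.07) and that of Ank3 -0.22 (-0.48 to 0.04). Tfdp2, called after T4 (-0.52) but not after T3 (-0.13), differed by -0.39 (-0.61 to -0.17, adjusted p = 0.0903 with edgeR). Nr5a2, Ank3 and Tfdp2 fell, so their estimates lay further from vehicle after T4 than after T3. Tlcd2 differed by -0.57 (-0.89 to -0.26, adjusted p = 0.0764), Trim7 by -0.53 (-0.93 to -0.13, adjusted p = 0.217) and Akr1c18 by -1.35 (-2.05 to -0.65, adjusted p = 0.0613). Fasn differed by -0.33 (-0.68 to 0.01) and Hmgcs1 by -0.16 (-0.48 to 0.17). Over all genes the median distance from the difference to its 95% bound was 0.24.

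Of the 70 genes called after T4, 63 were also called after T3 in the same direction and 0 in the opposite one. Of the 1155 genes called after T3, 78 passed the test between T4 and T3. Because both comparisons use the same 5 vehicle livers, some overlap arises without any shared response. The overlap of 63 compared with 2.4 for independent lists. With the vehicle livers split between the comparisons, the observed overlap was 7 on average (2 to 18). Each comparison then kept only 2 or 3 vehicle livers, so the drop mixes lost sharing with fewer libraries and 7 is no chance value. The covariance of log2 changes was 0.0873 and the correlation 0.43 in these splits. With all vehicle livers the covariance was 0.13 against 0.0327 in simulated unchanged groups that shared them, and the correlation 0.774 against 0.591. For T4 and T3+T4, 64 genes were shared (independent 5.5, split 11.4, covariance 0.0999 against 0.0328), with a correlation of 0.591 that did not exceed the simulated 0.61, and for T3 and T3+T4, 833 (90.9, 152.4, 0.158 against 0.0327), with a correlation of 0.70 against 0.582.

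**Figure D5:**
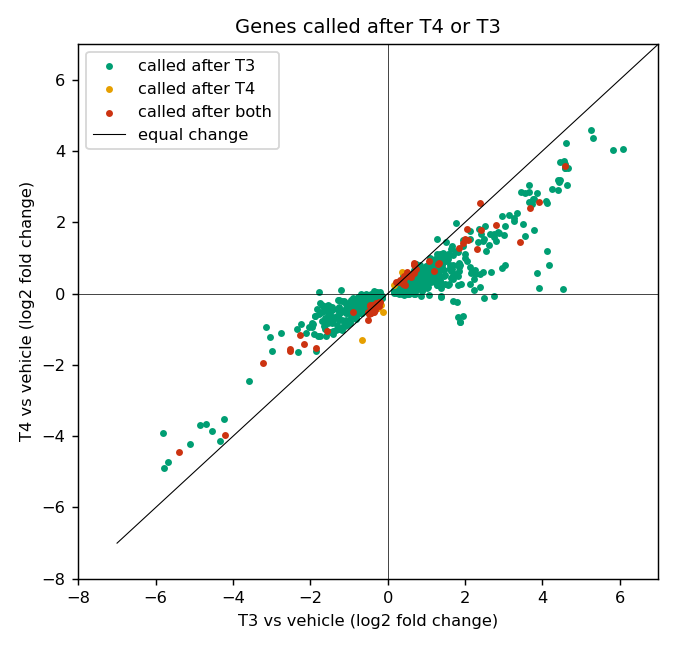
Log2 fold change against vehicle after T4 (vertical) and after T3 (horizontal) of the genes called after either hormone, with the line of equal change. Of the 70 genes called after T4, 63 were also called after T3 in the same direction.

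Adding T3 to T4 raised 20 of 24 cholesterol, 5 of 20 lipogenesis and 7 of 17 thyroid hormone induced genes. Against T4 alone, Col4a3 was 53.8 ± 45.2 CPM (SD, n = 7) against 2.79 ± 1.11 (n = 8), a log2 change of 4.26 ± 0.53 (adjusted p = 1.59e-05). Serpina9 rose by 4.09 ± 0.53 and Slc6a11 by 3.97 ± 0.58, while Vldlr (-2.19 ± 0.34), Dio3 (-1.57 ± 0.34) and Abcc3 (-1.37 ± 0.22) fell. Of 24 cholesterol genes 20 rose and 0 fell, with 21 adjusted over the list alone (median 0.94, camera adjusted p = 6.73e-33, and 0.0167 with an estimated correlation). Of 20 lipogenesis genes 5 rose (6 adjusted over the list alone, camera adjusted p = 2.44e-06, and 0.0266 with an estimated correlation) and of 17 thyroid hormone induced genes 7 (9 higher and 1 lower adjusted over the list alone, 6.11e-09 and 0.00116). Of 25 fatty acid oxidation genes 12 fell (13 adjusted over the list alone, camera adjusted p = 1.31e-11, adjusted p = 0.107 with an estimated correlation) and of 11 fetal genes 7 (8 adjusted over the list alone, 7.52e-07, adjusted p = 0.0572). With the library total as a covariate 4 and 3 of these fell. Of 8 acinar genes 8 rose (camera adjusted p = 2.34e-07, adjusted p = 0.0944 with an estimated correlation), in 3 of 7 T3+T4 and 0 of 8 T4 libraries with an acinar mean of at least 5 CPM. In all 693 genes rose and 776 fell. Leaving out T4 animal 70 or T3+T4 animal 72 gave 972 or 947 genes, the animals 54 to 85 gave 703, the library total as a covariate 768, and leaving out libraries with raised acinar or muscle genes 143.

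Adding T4 to T3 raised 2 genes and lowered 0 with edgeR. Aacs rose from 13.4 ± 4.53 CPM after T3 (SD, n = 6) to 34.2 ± 12.7 after T3+T4 (n = 7, log2 fold change 1.34 ± 0.22, adjusted p = 0.0197). Tkt, a transketolase of the pentose phosphate pathway, rose from 85.2 ± 7.44 to 110 ± 8.96 CPM (0.37 ± 0.06, adjusted p = 0.0197). Both calls ended without T3 animal 61 or T3+T4 animal 72, 84 or 85, each leaving 0 genes. Leaving out T3 animals 60, 62, 65 or 68 gave 40, 33, 18 or 34 genes and T3+T4 animals 78 or 79 gave 110 or 31. The count was 155 with DESeq2 and 91 with the library total as a covariate, and 2165 genes had an unadjusted p under 0.05.

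Against control livers the 3 treatments left different numbers of genes changed. After T4, 312 genes were higher and 292 lower than in control. Dlk1 stayed higher (3.34 ± 0.42, adjusted p = 4.06e-05), as did Asprv1 (2.91 ± 0.62) and Olfm4, a granulocyte protein (2.39 ± 0.67), while Amy2a1 (-3.82 ± 0.46), Amy2a4 (-3.47 ± 0.51) and Amy2a2 (-3.46 ± 0.49) were lower. The call of Olfm4 was lost without any 1 of the 5 control animals or T4 animal 54, 58, 69, 70 or 71 (adjusted p up to 0.28). Of 24 cholesterol genes 9 were lower after T4 than in control, with 16 adjusted over the list alone (median -0.58, camera adjusted p = 1.46e-12, adjusted p = 0.226 with an estimated correlation). Of 17 thyroid hormone induced genes 2 were lower (5 adjusted over the list alone, camera adjusted p = 3.93e-05, and 0.0274 with an estimated correlation). Leaving out control animals 42, 49, 50 or 59 gave 302, 165, 216 or 388 genes in the T4 comparison, and T4 animals 40, 46, 69, 70 or 71 gave 1024, 386, 378, 350 or 372. The count was 306 with no filter, 292 with the sex covariate, 147 with acinar and muscle covariates and 86 without the libraries with raised acinar or muscle genes.

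After T3, 29 genes were higher and 7 lower than in control. Dlk1 (2.56 ± 0.43, adjusted p = 0.00593), Cxcr2 (2.32 ± 0.48) and Myom1, a sarcomere protein (2.29 ± 0.43), were higher, and Sprn (-1.80 ± 0.37), Angptl2 (-1.41 ± 0.24) and Epha3, an ephrin receptor (-0.83 ± 0.14), were lower. Leaving out control animal 42 or 49 ended the calls of Cxcr2, Myom1 and Sprn, as did T3 animal 61 or 64 for Cxcr2 and Sprn and control animal 50 or 59 for Cxcr2 (adjusted p up to 0.252). Of 19 cell cycle genes 0 passed with edgeR and 16 were lower adjusted over the list alone (median -0.95, camera adjusted p = 7.89e-13, adjusted p = 0.597 with an estimated correlation). Leaving out control animals 42, 49 or 50 gave 13, 8 or 16 genes, and T3 animals 60, 61, 62, 64 or 65 gave 67, 15, 267, 19 or 114. The muscle mean was at least 5 CPM in 2 of 6 T3 and 0 of 5 control libraries, and Ckm had 0 reads above the added 1 and Acta1 12 over the control livers (adjusted p = 0.0769 each). The count was 12 with acinar and muscle covariates, 1 without the libraries with raised acinar or muscle genes, 9 with the library total as a covariate and 338 with DESeq2.

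After T3+T4, 0 genes differed from control with edgeR, 1226 had an unadjusted p under 0.05, and DESeq2 called 50, all lower. Dlk1 averaged 29.3 ± 10.9 CPM (SD, n = 7) against 5.58 ± 3.17 in control (n = 5). Its log2 fold change was 2.37 (95% interval 1.51 to 3.23), without passing the edgeR test over all genes (adjusted p = 0.0714). Camera at the preset correlation called 18 of 27 lists in this comparison, and with an estimated correlation it called 0. The lists of cholesterol genes (median 0.44, camera adjusted p = 2.68e-10) and fatty acid oxidation genes (-0.11, 3.82e-06) had an adjusted p = 0.317 and 0.342 with an estimated correlation. Leaving out control animal 47, T3+T4 animal 72 or T3+T4 animal 78 gave 1, 4 or 1 genes.

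Of the 1642 genes that differed between vehicle and control livers, 56 moved back with a call after T4, 522 after T3 and 1192 after T3+T4, and 0 moved further. Of the 1642, 441 were still called against control after T4, 26 after T3 and 0 after T3+T4. These comparisons share the vehicle livers, which gives opposite changes by chance. The 56, 522 and 1192 opposite calls compared with 3.4, 55.5 and 129.8 for independent lists. With the vehicle livers split they were 9.4, 101.3 and 274.8 on average. The splits leave fewer vehicle livers per comparison, so these are observed values and not chance values. The covariances were -0.102, -0.14 and -0.192 against simulated values of -0.0324, -0.0325 and -0.0325, and the correlations -0.58, -0.595 and -0.812 against -0.554, -0.53 and -0.547.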

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

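The tests of the count ceiling, of the hormone response of abundant genes, of mixed RNA and of pancreas RNA, the library total covariate and the settings that leave out libraries by sex or tissue genes were chosen only after the results were seen.

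The abundant genes of the liver were lower after T3+T4. The 106 genes above 50% of the ceiling of 2 counts per exonic base fell on average by 0.20 on the log2 scale between vehicle and T3+T4 livers (95% interval -0.31 to -0.08). Within groups their mean level had a slope of -0.76 (95% interval -0.84 to -0.67) on log2 library total, which a ceiling on counts met by larger library totals would give. With the library total as a covariate the change was 0 (-0.04 to 0.03), 0.85% of it, so the counts show no change of the set beyond the library total. Counts near a ceiling would show little of a real change, so this does not exclude a hormone response of these genes. Changes of single abundant genes such as Alb after T3 or T3+T4 may thus reflect library size.

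The sex genes of 4 animals differed from the sex in their labels, of 20 animals with a labelled sex. T4 animal 54, vehicle animal 67 and T3+T4 animal 79 are labelled female but expressed Y-linked genes, and T3 animal 68 is labelled male but expressed Xist. In these 4 the signal of the labelled sex was at most 5.18% of its usual level. This argues against RNA of the labelled sex as a main part of these libraries. A smaller mixture stays open across the series, since the signal of the other sex reached 9.64% among the other 27. In all, 7 libraries had over 5%. Whether libraries were swapped between groups cannot be told apart from wrong sex labels, since 3 of the 4 lay nearest to the mean of their own group, as did 19 of the other 27, while vehicle animal 67 lay nearest to T4 livers. T4 animal 46, which has no labelled sex and expressed Y-linked genes, lay nearest to vehicle livers, and T4 animal 54 to its own group. An exchange of vehicle animal 67 with either would leave the female label of animal 67 on a library that expressed Y-linked genes. No biological explanation was tested.

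Pancreatic acinar genes were high in some libraries of a group and low in the rest. The 6 acinar genes other than Amy2a5 and Cela1 rose and fell together within groups, with a median pairwise correlation of 0.93 (lowest 0.543), which pancreas RNA in some libraries would give. A hormone response of the acinar genes stayed open, since a Kruskal-Wallis test between the groups had a permutation p of 0.107 over 100000 draws, which did not pass, and the groups held 28.5% of the variance. Cela1 and Amy2a5 followed the other acinar genes less closely (correlations of 0.171 and 0.266).

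The interaction asked whether T4 acted differently with and without T3, and 23 genes passed. The log2 effect of T4 on 9030619P08Rik was 3.57 alone and 0.21 when T4 was added to T3 (difference -3.36 ± 0.34, adjusted p = 1.57e-06), and on Sbk1 0.90 and 0.15 (-0.75). The effects on Nt5e were 0.82 and 0.02 (-0.80) and on Cyp3a44 1.93 and -0.23 (-2.16), both genes chosen after their values were seen. Of 8 acinar genes 5 passed and went the other way, Cel (10.97), Clps (8.62), Ctrb1 (9.22), Cpa1 (8.62) and Cela3b (7.94), and the list had an adjusted p = 0.111 with an estimated correlation. The pancreatic enzyme genes Prss2 (9.45) and Cpb1 (8.33), chosen after their values were seen, also passed. Cel had 1 read over the T3 livers and 8 over the T4 livers, and Clps 2 and 11, so their fitted changes depend on the prior count and are no bounds (13.96 and 10.92 with the added 1 subtracted). With acinar and muscle covariates 1 gene passed, and with the libraries with raised acinar or muscle genes left out edgeR called 0 (869 genes had an unadjusted p under 0.05, and DESeq2 with all libraries called 109). Leaving out vehicle animal 37 gave 1 gene, T4 animals 46 or 71 gave 3 each, and T3 animals 60, 61, 62, 64 or 65 gave 5, 3, 39, 10 or 3. Of 60 splits of the libraries, 2 gave as many calls, a share under the limit fixed beforehand, with the highest other split at 335 against the real 23. The splits also break up the effects of each hormone alone, so they cannot decide whether chance gave the interaction calls. A split with several times the real count points to a structure of the samples.

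Of 545 groups of libraries checked, 29 held a single library far from the rest, against 27.2 that chance would give at about 1 in 20. T4 animal 40 had 5 of the 29, each on the side of the control mean, and lay nearest to control livers, and the 3 of vehicle animal 67 lay on the side of the T4 mean. In control livers, with the range of the others in brackets (all in CPM), Akr1c18 was 3.3 in animal 42 (23.8 to 47.6), and animal 47 had Cel at 22.5 (0.183 to 0.79), Clps at 6.43 (0.191 to 0.395) and Cyp4a10 at 253 (110 to 129). In vehicle livers, animal 67 had Abcc3 at 254 (378 to 420), Cyp3a44 at 44.9 (17.3 to 21) and Srebf2 at 110 (77.2 to 84.9). Vehicle animal 55 had Dio3os at 37.8 (54.2 to 61.6), Ier3 at 21.2 (13.1 to 14.7) and Vldlr at 198 (102 to 123), and vehicle animal 37 had Slc6a11 at 0.365 (0.184 to 0.212), which is 1 read, with the added 1 alone in the others.

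After T4, animal 40 had Ces4a at 1.22 (0.175 to 0.529), Peg3 at 322 (736 to 1200), Plagl1 at 38.9 (76.3 to 128), Slc16a10 at 208 (61.1 to 96.3) and Tlcd2 at 162 (83.3 to 114). Animal 54 had Cel at 1.05 (0.176 to 0.482) and Ctrb1 at 6.29 (0.176 to 1.22). After T3, Alb was 625 in animal 62 (467 to 516), Asprv1 22.3 in animal 64 (3.61 to 5.18), Cel 0.298 in animal 60 (0.151 to 0.193, likewise 1 read against the added 1 alone) and Fads2 210 in animal 68 (169 to 181). T3 animal 61 had Kank2 at 72.4 (111 to 122), Marveld1 at 57 (84 to 104) and Slc16a10 at 712 (153 to 258), and T3 animal 60 had Trim7 at 36.1 (21.1 to 25.5). After T3+T4, Angptl2 was 81.6 in animal 72 (28.9 to 44.1), Fads2 227 in animal 85 (174 to 194) and Pax8 0.334 in animal 80 (1.47 to 2.98).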

How the results depend on the processing

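The settings with the added 1 subtracted, the ceiling correction, the library total covariate, the 4 animals left out by sex and the acinar and muscle settings were chosen only after the data were seen. No paired analysis was possible because the groups share no replicate (animal) numbers. The main counts were 1642 for vehicle against control, 70 for T4, 1155 for T3 and 2692 for T3+T4 against vehicle, 94 for T4 against T3, 1469 and 2 for T3+T4 against T4 and against T3, 604, 36 and 0 for T4, T3 and T3+T4 against control, and 23 for the interaction. Counts not given for a setting stayed within 1.5 times these where it was run, and only animals 54 to 85 was run for the 6 comparisons among triple mutant groups alone. With median-of-ratios factors, scaling by library total and subtraction of the added 1 all did. Another scaling moved the median of all genes by at most 0.04.

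With no filter 34 genes were called for T4, 13 for T3+T4 against T3, 306 for T4 against control and 14 for the interaction, and with a mean of at least 5 CPM the interaction had 10. With only the groups compared, fewer libraries in the fit, the counts were 25 for T4, 275 for T3, 8 for T4 against T3, 0 for T3+T4 against T3 and 11 for T3 against control. DESeq2 called 235 for T4, 234 for T4 against T3, 155 for T3+T4 against T3, 338 for T3 and 50 for T3+T4 against control, and 109 for the interaction. With the sex covariate the counts were 587 for T3, 8 for T4 against T3, 1 for T3+T4 against T3, 292 for T4 against control and 2 for T3+T4 against control. With only animals 54 to 85, fewer libraries, they were 8 for T4, 167 for T3, 794 for T3+T4, 43 for T4 against T3, 703 for T3+T4 against T4 and 0 against T3. Apart from the smaller number of libraries, the cause was not tested.

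The ceiling correction gave 15 for T3+T4 against T3. With the library total as covariate the counts were 524 for T3, 21 for T4 against T3, 768 for T3+T4 against T4, 91 for T3+T4 against T3 and 9 for T3 against control. With the 4 animals with another labelled sex left out they were 763 for T3, 38 for T4 against T3, 37 for T3+T4 against T3 and 9 for the interaction. With acinar and muscle covariates they were 22 for T4, 463 for T3, 866 for T3+T4 against T4, 1 against T3, 147 for T4 and 12 for T3 against control, and 1 for the interaction. With the libraries with acinar or muscle genes left out, fewer libraries, they were 689 for vehicle against control, 1 for T4, 83 for T3, 685 for T3+T4, 0 for T4 against T3, 143 for T3+T4 against T4, 86 for T4 and 1 for T3 against control, and 0 for the interaction. The cause was not tested.

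Leaving out each library in turn (leave-one-out) gave 935 to 1604 genes for vehicle against control, 14 to 93 for T4, 622 to 1570 for T3, 1879 to 2831 for T3+T4, 27 to 342 for T4 against T3, 947 to 1738 for T3+T4 against T4, 0 to 110 for T3+T4 against T3, 165 to 1024 for T4, 8 to 267 for T3 and 0 to 4 for T3+T4 against control, and 1 to 39 for the interaction.

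Of 427 calls of named genes, 311 held without any 1 library, 426 with DESeq2, 369 with no filter and 332 with acinar and muscle covariates, and 211 of 419 with the libraries with acinar or muscle genes left out. With the sex covariate 360 held and with the library total as covariate 366. With only the groups compared 327 of 406 held, and with only animals 54 to 85 161 of 279. After reversal Alb was at 0.01 for T3+T4 against vehicle (library total as covariate), and with acinar and muscle covariates Clps was at -0.28 and Ctrb1 at -0.04 for T3+T4 against T4. Of 50 calls of gene lists in the 5 main comparisons, 6 held with an estimated correlation and 20 with fry.

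The overlap of T4 and T3 calls was 63, with a mean of 7 over split vehicle libraries and 7 at an adjusted p under 0.01. For T4 and T3+T4 these were 64, 11.4 and 10, and for T3 and T3+T4 833, 152.4 and 253. Opposite calls of vehicle against control with T4 were 56, 9.4 and 10, with T3 522, 101.3 and 167, and with T3+T4 1192, 274.8 and 445. Simulated 1.5-fold changes were recovered in 29.9% (interaction) to 68.7% of cases, and the simulations did not vary depth, so what depth alone limits was not tested.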

Other observations

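The test of T4 as a weaker form of T3 was chosen only after the results were seen. Cholesterol genes passed the list tests when T4 was added to T3. With edgeR 0 of 24 passed over all genes, while 23 were higher adjusted over the list alone (median 0.84, camera adjusted p = 6.04e-34, and 0.0276 with an estimated correlation, fry 0.00319), and 8 passed with the library total as a covariate. In the same comparison edgeR called 0 of 19 cell cycle genes (median 0.57, camera adjusted p = 1.63e-09, adjusted p = 0.332 with an estimated correlation) and 0 of 10 granulocyte genes (median -0.98, camera adjusted p = 0.000253, adjusted p = 0.404 with an estimated correlation). For T3 against control edgeR called 0 of 10 granulocyte genes over all genes and 7 as higher adjusted over the list alone (median 1.28, camera adjusted p = 3.8e-05, adjusted p = 0.618 with an estimated correlation). Xist-expressing libraries numbered 4 of 5 control, 2 of 5 vehicle, 2 of 8 T4, 5 of 6 T3 and 2 of 7 T3+T4 libraries. The T3 and control groups thus differed from the vehicle, T4 and T3+T4 groups in sex as well as in hormone or genotype. The sex covariate lowered the count for T4 against T3 from 94 to 8. It also lowered the counts given above for T3 against vehicle and T4 against control. The count for vehicle against control stayed within 1.5 times the main count.

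A hypothesis is that the T4 response may be a weaker form of the T3 response rather than a program of its own. The genes 9030619P08Rik, Dio1, Nt5e, Sned1, Abhd6 and 1810064F22Rik were called both after T4 against vehicle and between T4 and T3, the last with an adjusted p of 0.0497 between T4 and T3 (0.0299 to 0.509 over its 27 other settings, of which 20 ended the call). Leaving out 1 library could end the call after T4 against vehicle for Dio1, Sned1, Abhd6 and 1810064F22Rik. It could end that between T4 and T3 for Nt5e, Sned1, Abhd6 and 1810064F22Rik. Only 9030619P08Rik kept both calls without any 1 library. If the T4 response is a weaker form of the T3 response, these 6 genes would lie between vehicle and T3, and 0 of the 6 lay outside that range. These 6 are a small part of the 70 genes called after T4. Named genes not called between the hormones included Tfdp2, Ank3 and Nr5a2, whose estimates lay beyond T3. For Tfdp2 the T4 minus T3 difference was -0.39 (95% interval -0.61 to -0.17, adjusted p = 0.0903 with edgeR). The doses are not in the labels, so a lower effective dose and a lower activity of T4 are not separated.

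Chance was excluded as the source of the counts that no other split reached, by regrouping the libraries 60 ways, the real grouping included. For vehicle against control 1 of 60 splits had as many calls (real 1642, highest other 329), for T4 against vehicle 1 (70, 20), for T3 1 (1155, 273), for T3+T4 1 (2692, 126), for T3+T4 against T4 1 (1469, 17) and for T4 against control 1 (604, 263). For T4 against T3, 2 splits had as many (94, highest other 459), and for T3 against control 2 (36, 355). These shares were under the limit fixed beforehand, but in both comparisons another split gave several times the real count. Regrouped libraries can thus give such counts, so chance stays open there. A split of this kind points to a structure of the samples. For T3+T4 against T3, 3 splits had as many (2, highest other 28), so chance was not excluded, and the 28 likewise points to a structure of the samples. For T3+T4 against control the real count with edgeR was 0 (1226 at an unadjusted p under 0.05, 50 with DESeq2), so all 60 splits had as many by construction (highest other 13) and they say nothing about chance.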
